A study of Homo sapiens with 11 samples.

How the data were processed

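Bone marrow mononuclear cells of 9 patients with CKD and 2 healthy donors were profiled, 1 library per person. Per the labels' protocols, marrow was shipped overnight, mononuclear cells were isolated the next day and frozen, and libraries were made with the Scipio Asteria kit, which captures single cells on barcoded beads in a reversible hydrogel, and processed with the Cytonaut software. The submitters' processing notes name Scanpy and the genome build GRCh38, with no versions. The aligner, the gene annotation, the rule for calling cells and any batch of library preparation or sequencing are not given in the sources used here. The deposited values were raw UMI counts per gene and barcode, whole numbers that had not been normalized, in a matrix of 36601 genes for each library, with 10989 barcodes in all. As the number of barcodes was the same in every library, the authors' cell calling may have been a fixed number of top barcodes, and barcodes with few genes were removed here.

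Groups were taken from the sample labels (2 healthy, 3 primary FSGS, 4 secondary FSGS and 2 non-FSGS libraries). No 2 libraries shared more than 15 barcodes over the 55 pairs, and a chi-square test of summed counts gave 8.08 to 38.9 per degree of freedom in the 11 pairs within a group, so that no library was counted as a copy of another. Gene identifiers were matched to GENCODE release 29 (GRCh38), where 34616 of 36601 were found, and coordinates are those of that annotation. Y-linked genes, XIST and TSIX (103 genes) were removed before any test. HLA genes, GSTM1, GSTT1 and immunoglobulin and T cell receptor segments other than constant ones were tested but not named, and another gene was added to these after its values had been seen.

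Barcodes with fewer than 200 genes or over 20% mitochondrial UMIs were removed, leaving 8543 of 10989. Scrublet, run per library within scanpy 1.11.5 (Python 3.11.15), called 58 doublets (0.68%), which were removed, leaving 8485 cells. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes and 30 principal components were used with 15 neighbours, and cells of all libraries were clustered together by the Leiden method (igraph 0.11.9) at resolution 1, with no integration across libraries. A cluster took the name of the class with the largest share of its fixed markers at 2 or more times the CPM of all other cells and seen in at least 10% of its cells, with at least 3 such markers, and is called "-like" for that reason. The 11 classes with a mean share of at least 1% were compared between groups by exact two-sided permutation tests of the difference in mean share, with 55, 36 and 35 possible splits and Benjamini-Hochberg adjustment over the classes of a comparison.

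For gene tests the raw counts of a class were summed per library, with at least 20 cells in each, and fitted with edgeR 4.0.16 (R 4.3.3; quasi-likelihood test, robust, TMM scaling, filterByExpr) in 1 model of the 4 groups with 7 residual degrees of freedom. Healthy donors were compared with the unweighted mean of the 3 patient groups, non-FSGS with the mean of primary and secondary FSGS, and primary with secondary FSGS, and each patient group was compared with healthy donors in all cells. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. Sums held 1016034 to 4357829 counts per library in all cells and 82283 to 811939 in monocyte-like cells (54 to 392 cells). Myeloid progenitor-like and erythroid-like cells did not reach 20 cells in 2 libraries of every group. They were run with a rule set after the cell numbers had been seen, of at least 10 cells, 2 healthy libraries and 1 or more libraries in each patient group. For myeloid progenitor-like cells this left the same 10 libraries as a minimum of 20, with 1 non-FSGS library, and for erythroid-like cells it raised the libraries from 6 to 8. Where the text says that a gene was higher or lower in a number of libraries, those libraries lay beyond all libraries of the other group.

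Gene lists were tested with camera (limma 3.58.1) on log2 CPM of the summed counts with a prior count of 2, with the preset correlation of 0.01, and again with an estimated correlation and with fry. There were 31 lists with at least 3 tested genes in all cells. fry asks whether a list's genes move one way and does not compare them with other genes. Named genes were chosen by a fixed rule: up to 10 higher and 10 lower genes with the smallest p among those passing with a mean of at least 5 UMIs per library, up to 4 members with the smallest p from each list described, and PLAUR. Of the genes so chosen, 2 are not reported here. Alternatives were DESeq2 1.42.0, RLE scaling, no filter on low counts, sums thinned to the smallest total, doublets kept, at least 500 genes per cell, the compared groups only, a 2-group fit, removal of hemoglobin, immunoglobulin, mitochondrial and ribosomal protein genes, Leiden resolution 2, marker scores per cell with and without thinning each cell to 500 UMIs, removal of barcodes 1 mismatch from a larger one, leaving out libraries under 650 kept cells, a block on the label number, and leaving out each library in turn.

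The edgeR step was tested on simulated data with 200 changed genes. For patients against healthy donors in all cells (11689 genes) it recovered 8 of 100 genes changed by 2-fold and 65 of 100 changed by 4-fold, with 2 false calls. In monocyte-like cells (5568 genes) it recovered 11 and 77 of 100, with 5 false calls. Changes of 2-fold were thus mostly missed with 2 healthy libraries. Free RNA from other cells was not removed.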

Results

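Single-cell RNA sequencing was carried out on bone marrow mononuclear cells in 11 libraries, 9 from adults with chronic kidney disease (CKD) and 2 from healthy donors. The patients had received a kidney transplant in which disease had come back. Their libraries were labelled primary focal segmental glomerulosclerosis (FSGS, a scarring of the kidney's filtering units) in 3 cases, secondary FSGS in 4 and a kidney disease other than FSGS (non-FSGS) in 2. The healthy marrow was bought from a commercial supplier, so that health, the patients' transplant and the source of the marrow cannot be told apart in any comparison with it. The libraries held 10989 barcodes, the same number each, and between 1043758 and 4388321 unique molecular identifier (UMI) counts. After filtering, 8485 cells were kept, 503 to 959 per library, with a median of 1460 to 2448 UMIs per cell. Each library came from a different person, and values are given as mean ± SD over libraries or as a log2 fold change ± SE. The SE was derived from the quasi-likelihood test, as the size of the log2 fold change over the square root of the F statistic.

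The marrow held cells of the main lineages in all 4 groups, from CD34-positive stem and progenitor (HSPC)-like cells to mature myeloid, lymphoid and erythroid cells. Monocyte-like cells made up 27.0 ± 17.8% (SD, n = 9) of the patients' kept cells and 28.5 ± 5.30% (n = 2) of the healthy ones. T-like cells held 13.1 ± 11.3% against 10.2 ± 2.58%, cytotoxic lymphocyte-like cells 10.2 ± 4.66% against 6.58 ± 0.129%, and B-like cells 6.95 ± 2.97% against 9.05 ± 0.265%. Plasmacytoid dendritic-like cells, the main producers of type I interferon, took 1.24 ± 0.772% of the patients' cells and 3.10 ± 0.329% of the healthy cells, and all 9 patient libraries lay below both healthy ones. That is the smallest p the 55 splits of the libraries can give (exact two-sided permutation test, p = 0.0182), and it became 0.2 after adjustment over the 11 classes tested. No class passed after adjustment in any of the 3 comparisons, and a single class at the smallest p could not have done so. Clusters that no marker set named held 15.4% of the kept cells (14.0 ± 6.83% in patients and 16.6 ± 3.68% in healthy donors). The largest, of 681 and 560 cells, both had EPCAM, ALDH1A1 and NMU among their top genes. At Leiden resolution 2 a cluster of 276 cells with EPCAM and AKR1C3 among its top genes was named erythroid. The erythroid-like class may therefore leave out cells of that lineage.

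**Figure D1:**
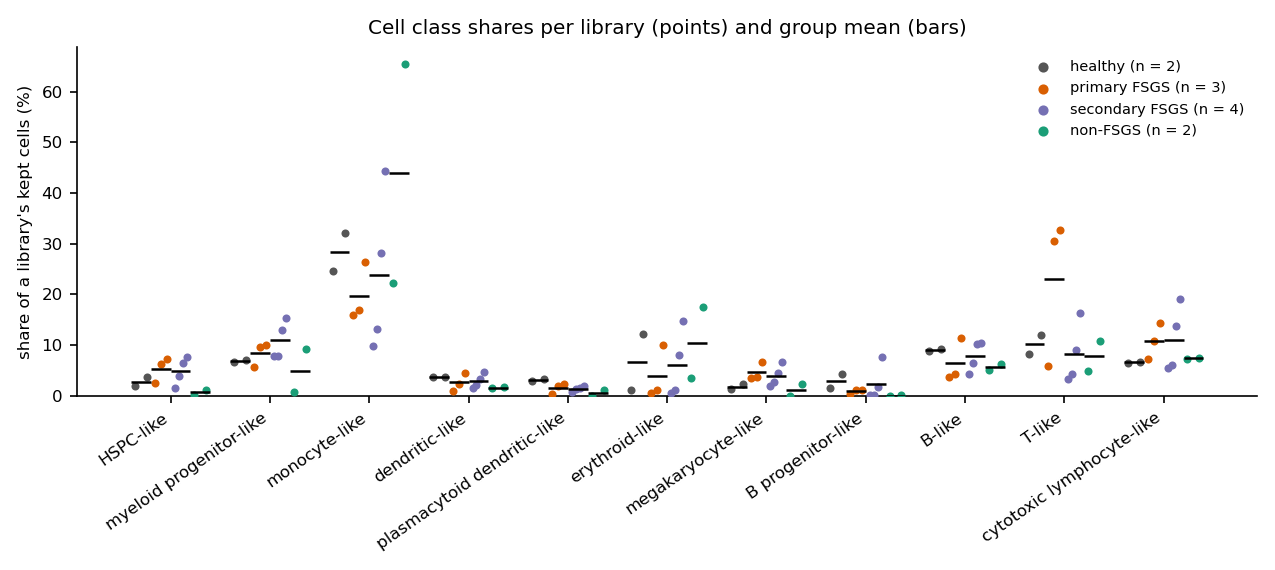
Share of each library's kept cells (percent, vertical axis) in the 11 cell classes tested (horizontal axis), by group. Each point is a library and each bar a group mean; the plasmacytoid dendritic-like shares of all 9 patient libraries lie below those of the 2 healthy libraries, and the HSPC-like shares of the 7 FSGS libraries lie above those of the 2 non-FSGS libraries.

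The first comparison asked how marrow of CKD patients differs from healthy marrow. In the counts summed over all cells of a library, interferon response genes rose as a group in the patients, with a median log2 fold change of 1.09 over 16 tested genes, 15 of them positive (camera, adjusted p = 8.51e-07). Immediate early genes, transcription factors and phosphatases induced within minutes of a stimulus, rose as a group with a median of 0.83 and all 17 positive (adjusted p = 8.51e-07). Plasma cell genes fell, with a median of -0.65 and all 12 negative (adjusted p = 8.51e-07). These 3 calls were lost when the correlation between list members was estimated from the data, with adjusted p = 0.782 for interferon response, 0.813 for immediate early and 0.408 for plasma cell genes.

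No single gene passed. Among 11983 genes tested in all cells, edgeR called 0 between patients and healthy donors, with 298 at an unadjusted p under 0.05, and DESeq2 called 0. In the interferon list, none of the 16 members passed over all genes or adjusted over the list alone. XAF1, an interferon-induced promoter of apoptosis, measured 75.9 ± 24.0 CPM (counts scaled to a common total per library, n = 9) in patients and 31.8 ± 3.04 CPM (n = 2) in healthy donors (log2 fold change 1.11 ± 0.32). The corresponding log2 fold changes were 1.38 ± 0.61 for ISG15, a ubiquitin-like modifier, 1.07 ± 0.45 for IFIT3 and 1.90 ± 0.83 for IFI44L. Of the 17 immediate early genes none passed on either count. NR4A1, an orphan nuclear receptor, measured 40.6 ± 27.3 CPM against 7.30 ± 2.44 CPM and was above both healthy libraries in 9 of 9 patient libraries (2.34 ± 0.81). FOSB was at 1.71 ± 0.62, NR4A2 at 1.40 ± 0.58 and DUSP1, a phosphatase of MAP kinases, at 0.90 ± 0.46. The 12 plasma cell genes also held no passing member on either count. IGHG1, the constant region of IgG1, was at 89.8 ± 101 CPM against 576 ± 117 CPM, and log2 fold changes were -1.39 ± 0.55 for MZB1, an antibody-secretion chaperone, -1.05 ± 0.45 for DERL3 and -0.48 ± 0.22 for XBP1. IFI44L was at 0.98 without 1 of the 2 non-FSGS libraries and DERL3 at -0.31 without 1 of the 2 healthy ones. Plasma-like cells were 0.502 ± 0.424% of the patients' cells and 1.06 ± 0.267% of the healthy ones, a class too small to be tested.

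A further 7 lists passed in all cells. Inflammatory cytokines and chemokines rose (median log2 fold change 1.13 over 13 genes, adjusted p = 0.000269), with IL1B at 2.38 ± 0.94, OSM at 1.54 ± 0.73 and the monocyte attractant CCL2 at 3.12 ± 1.56. The healthy means of IL1B and CCL2 were 4.29 and 0.780 CPM, near the floor. NF-kB targets rose (0.64 over 15 genes, 0.0214), with the inhibitor TNFAIP3 at 1.32 ± 0.57, as did cytotoxic effector genes (0.75 over 14 genes, 0.00342), with GZMA at 2.21 ± 1.11 and GZMK at 1.95 ± 0.99, and stem and progenitor genes (0.56 over 13 genes, 0.0334), with MECOM at 1.63 ± 0.69 and CRHBP at 1.36 ± 0.88. Transcripts of the mitochondrial genome fell (-0.27 over 13 genes, 0.000269), as did nuclear genes of oxidative phosphorylation (-0.15 over 17 genes, 0.0181; NDUFA4 -0.38 ± 0.17) and cell cycle genes (-0.25 over 18 genes, 0.0278; PCNA -0.38 ± 0.43). MT-ND1, a subunit of respiratory complex I encoded on the mitochondrial chromosome, measured 1743 ± 253 CPM in patients and 2702 ± 374 CPM in healthy donors (-0.62 ± 0.17, lower in 9 of 9) and was the 1 member of these 7 lists that passed adjusted over the list alone. MT-CYB was at -0.58 ± 0.20. With an estimated correlation, adjusted p = 0.813 for each of the 7 lists. HSPC-like cells were 4.13 ± 2.88% of the patients' and 2.81 ± 1.32% of the healthy cells, beside the stem and progenitor list, and cytotoxic lymphocyte-like cells 10.2 ± 4.66% and 6.58 ± 0.129%, beside the cytotoxic list. Of these 7 calls, the inflammatory one alone passed without each library in turn, and it ended without the 3 libraries under 650 kept cells (0.0927), where the median log2 CPM difference was 0.41 against 0.89. Without 1 of the 2 healthy libraries adjusted p = 0.978 for the stem and progenitor, 0.818 for the NF-kB, 0.895 for the cell cycle, 0.25 for the cytotoxic, 0.204 for the mitochondrial and 0.0659 for the oxidative phosphorylation list, which also had 0.106 without the other healthy library and 0.0663 without 1 non-FSGS library. The first 3 of these calls also ended without 1 primary FSGS library (0.146, 0.135 and 0.233), without 1 secondary FSGS library each (0.0525, 0.0599 and 0.0561) and without 1 non-FSGS library each (0.418, 0.419 and 0.419), and the stem and progenitor call ended with sums thinned to the smallest total (0.274). Without that first healthy library the median log2 CPM difference was -0.138 for stem and progenitor, 0.122 for NF-kB and -0.067 for cell cycle genes. It was 0.434 for cytotoxic, -0.233 for mitochondrial and -0.203 for oxidative phosphorylation genes. The last list had -0.145 without the other healthy library and -0.123 without 1 non-FSGS library. With thinned sums the stem and progenitor list had 0.404. IL1B was at 1.496 without 1 non-FSGS library, CCL2 at 2.28 and 2.30 without 1 healthy and 1 primary FSGS library, and MECOM at 0.97 without 1 healthy library.

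Within monocyte-like cells, the patients' immediate early, inflammatory and NF-kB target genes rose together. The immediate early list had a median log2 fold change of 0.89 over 17 genes, 16 of them positive (camera, adjusted p = 9.77e-09), and 6 of its members were higher adjusted over the list alone. The inflammatory list had a median of 1.37 over 10 genes (adjusted p = 9.34e-05, 3 higher adjusted over the list alone) and the NF-kB list 0.78 over 14 genes (adjusted p = 0.000163, 1 higher adjusted over the list alone). For each of these 3 lists, adjusted p = 0.169 with an estimated correlation. NR4A1 measured 102 ± 58.0 CPM in patients and 11.3 ± 8.40 CPM in healthy donors (2.99 ± 0.53, higher in 9 of 9, edgeR adjusted p = 0.0734), and was at 2.29 without 1 of the 2 healthy libraries. NR4A2 was at 1.53 ± 0.44, JUND at 0.93 ± 0.30 and DUSP1 at 0.81 ± 0.27. IL1B, the precursor of interleukin 1 beta, measured 97.1 ± 95.3 CPM against 4.23 ± 0.966 CPM (4.22 ± 1.12, higher in 9 of 9). IL1B and NR4A1 had means of only 24.3 and 31.5 counts per library, and their healthy levels lay near the floor. The size of these 2 changes is therefore uncertain. VEGFA was at 1.55 ± 0.52 and the neutrophil attractant CXCL2 at 1.21 ± 0.42. CD83, an activation marker of antigen-presenting cells, measured 330 ± 193 CPM against 69.7 ± 5.71 CPM (2.22 ± 0.57, higher in 9 of 9) and NFKBIA was at 1.14 ± 0.39. Over all 6230 genes tested in these cells edgeR called 0, with 463 at an unadjusted p under 0.05, whereas DESeq2 called 11.

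PLAUR encodes the urokinase receptor uPAR, whose soluble form has been studied as a circulating factor in FSGS, and was fixed for testing before the data were examined, as were the gene lists, cell markers and comparisons. It has the identifier ENSG00000011422 and lies on chromosome 19 from 43646095 to 43670547 (GRCh38). In monocyte-like cells PLAUR measured 646 ± 257 CPM in patients (n = 9) and 317 ± 6.38 CPM in healthy donors (n = 2), a log2 fold change of 1.04 ± 0.34 that was positive in 9 of 9 patient libraries. It did not pass over all genes (edgeR, adjusted p = 0.623) and passed adjusted over the uPAR list alone (adjusted p = 0.0412), where it was the 1 passing gene of 8. The uPAR list as a whole did not pass (median 0.25, adjusted p = 0.231).

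Of the other lists in monocyte-like cells, 8 passed. Interferon response genes rose (median log2 fold change 0.76, 10 of 11 positive, adjusted p = 0.00197), with ISG15 at 48.7 ± 36.5 CPM against 7.57 ± 3.19 CPM (2.25 ± 0.74) and IFI44L at 1.39 ± 0.64. Calprotectin and alarmin genes rose (0.53, 9 of 9 positive, 0.00515), with S100A4 at 1718 ± 325 CPM against 877 ± 129 CPM (0.95 ± 0.24, the 1 member passing adjusted over the list alone), ANXA1 at 0.83 ± 0.34 and S100A10 at 0.53 ± 0.23. Nonclassical monocyte genes rose (0.71, 6 of 9 positive, 0.00515), with the Fc receptor FCGR3A (CD16) at 2.38 ± 0.77 and MS4A7 at 1.11 ± 0.54. Chemokine receptor and homing genes (0.38, 0.0220; ITGAL 1.01 ± 0.39, SELPLG 1.36 ± 0.63), myeloid transcription factors (0.39, 0.0255; RUNX1 0.74 ± 0.40, KLF4 0.57 ± 0.34), complement and Fc receptor genes (0.32, 0.0277; C1QA 1.42 ± 0.88) and heat shock genes (0.56, 0.0316; HSP90AB1 0.64 ± 0.29, HSPA8 0.80 ± 0.43) also rose. Mitochondrial transcripts fell (-0.32, 11 of 13 negative, 0.0286), with MT-ND1 at -0.65 ± 0.28 and MT-CO3 at -0.40 ± 0.22. NR4A1, which is also an immediate early gene, was the 1 myeloid transcription factor passing adjusted over the list alone. With an estimated correlation, adjusted p = 0.169 for interferon response, calprotectin, homing, transcription factor and complement genes, 0.433 for nonclassical monocyte, 0.342 for heat shock and 0.622 for mitochondrial genes. With sums thinned to the smallest total 5 calls ended (adjusted p = 0.0936 for nonclassical, transcription factor and homing genes, 0.0909 for heat shock and 0.49 for complement), and the interferon list had too few genes to be tested. Without 1 of the 2 healthy libraries the calprotectin (0.12), transcription factor (0.476), heat shock (0.153), homing (0.121) and mitochondrial (0.111) calls ended, and without the other the nonclassical (0.167), complement (0.0584) and mitochondrial (0.0779) ones. The heat shock (0.104), complement (0.0677) and mitochondrial (0.107) calls ended without 1 of the 3 primary FSGS libraries, the last also without 1 secondary FSGS (0.0742) and 1 non-FSGS library (0.0595). C1QA was at 0.42 without that primary FSGS library and 0.71 without 1 healthy one, SELPLG at 0.75 without 1 healthy library and IFI44L at 0.72 without 1 non-FSGS library. The median log2 CPM difference of mitochondrial genes was -0.322 and -0.369 without each healthy library and -0.31 without that primary FSGS library. For transcription factors it was 0.008 without the first healthy library. With thinned sums it was 1.187 for nonclassical, 0.159 for transcription factor and 0.183 for homing genes. Heat shock genes had 0.423 there and complement genes 0.135.

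Different clusters made up the monocyte-like class in the 4 groups, and also in libraries of the same group. A cluster led by NAMPT, VCAN, CD300E and CD14 held 80.0 ± 12.3% of the healthy monocyte-like cells, 23.5 ± 30.9% of the primary FSGS, 4.44 ± 4.58% of the secondary FSGS and 26.6 ± 16.3% of the non-FSGS ones. A cluster led by HMOX1, CXCL8 and G0S2 held 12.6 ± 8.47%, 36.4 ± 38.5%, 3.88 ± 1.60% and 65.9 ± 16.5% in the same order. A cluster led by S100A9, S100A8 and FCN1 held 2.95 ± 4.18%, 29.1 ± 50.4%, 63.7 ± 35.8% and 1.83 ± 1.74%, and an FCGR3A and CDKN1C cluster 4.44 ± 0.310%, 10.8 ± 2.75%, 10.2 ± 8.06% and 5.74 ± 1.98%. The remaining cluster, led by THBS1 and NLRP3, came to 98.8% from a single library. The S100A9-led cluster ranged from 0 to 87.35% over the primary FSGS libraries and from 10.34 to 85.84% over the secondary FSGS ones. Comparisons within the class therefore compare mixtures of these clusters, and no difference in the mixtures was tested.

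**Figure D2:**
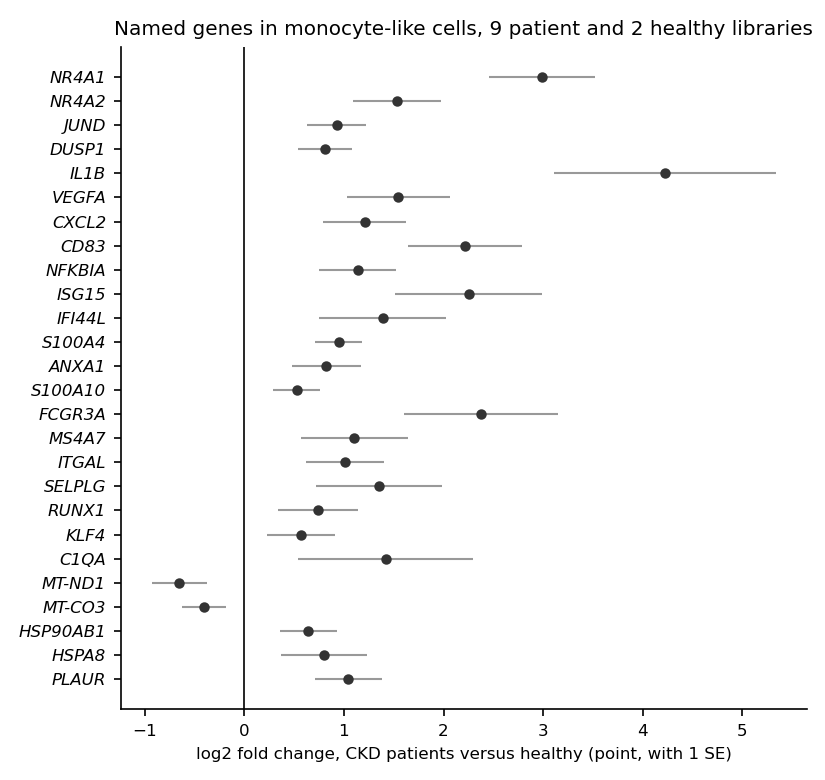
Log2 fold change of named genes in monocyte-like cells, CKD patients (n = 9) minus healthy donors (n = 2), with horizontal bars of 1 SE. NR4A1 (2.99) and IL1B (4.22) lie farthest to the right, and MT-ND1 (-0.65) and MT-CO3 (-0.40) lie left of 0; none passed over all 6230 genes.

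In the other classes, patients and healthy donors differed at 1 gene in each of 2 classes and at none in 3. In erythroid-like cells MT-ND1 was lower in patients, at 2115 ± 383 CPM (n = 6) against 4277 ± 602 CPM (n = 2) (-1.01 ± 0.17, lower in 6 of 6, edgeR adjusted p = 0.000491). In myeloid progenitor-like cells IGLC2, an immunoglobulin lambda constant gene of B and plasma cells, was lower, at 11.2 ± 9.42 CPM (n = 8) against 147 ± 153 CPM (n = 2) (-3.42 ± 0.65, adjusted p = 0.0108, from a mean of 5.2 counts per library). Without 1 of the 2 healthy libraries IGLC2 did not pass the filter on low counts and was not tested, so that its fall rests largely on that library. In the same cells PLAUR measured 268 ± 74.1 CPM against 110 ± 54.3 CPM (1.34 ± 0.38, higher in 8 of 8, adjusted p = 0.435). Free RNA from other cells was not removed, and its part in the IGLC2 value was not tested. Neither class had 20 cells in 2 libraries of every group. After the cell numbers had been seen, the erythroid-like set was run with a minimum of 10 cells and the myeloid progenitor-like set with 1 non-FSGS library, and neither gene was called by DESeq2, which called 0 genes in both. MT-ND1 was no longer called in erythroid-like cells without either of the 2 healthy libraries, while its log2 fold change ranged from -1.17 to -0.88 leaving out 1 library. In T-like, cytotoxic lymphocyte-like and B-like cells edgeR called 0 genes, with 140 of 3082, 191 of 2652 and 109 of 2238 at an unadjusted p under 0.05, and DESeq2 called 0 in each.

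Each patient group was also set against the same healthy donors in all cells, where edgeR called 0 genes for primary FSGS, secondary FSGS and non-FSGS, with 307, 762 and 364 at an unadjusted p under 0.05, and DESeq2 called 0, 2 and 1. The log2 fold change of NR4A1 was 1.63 ± 0.87 in primary FSGS, 2.65 ± 0.86 in secondary FSGS and 2.75 ± 0.93 in non-FSGS. That of PLAUR was 0.06 ± 0.46, 0.42 ± 0.44 and 1.82 ± 0.52. The small value in primary FSGS changed sign in several alternative fits, down to -0.24 without 1 of the 2 healthy libraries. In non-FSGS, PLAUR was at 1.09 and NR4A1 at 1.51 without 1 of the 2 libraries, and without 1 of the 3 primary FSGS libraries NR4A1 was at 0.90 in primary FSGS.

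The second comparison asked whether FSGS marrow differs from that of patients with other kidney disease. In monocyte-like cells 7 genes differed, 6 lower in FSGS and 1 higher (edgeR, adjusted p under 0.05 over 6230 genes), and each lay beyond both non-FSGS libraries in 7 of 7 FSGS libraries. GPR183, a receptor for oxysterols that guides immune cell migration, measured 150 ± 60.5 CPM in FSGS (n = 7) and 654 ± 11.4 CPM in non-FSGS (n = 2) (-2.09 ± 0.30, adjusted p = 0.00442). HIF1A, the oxygen-regulated subunit of hypoxia-inducible factor 1, measured 763 ± 135 CPM against 1916 ± 207 CPM (-1.32 ± 0.21, adjusted p = 0.00902). HMOX1, the heme-degrading enzyme heme oxygenase 1, measured 343 ± 190 CPM against 1936 ± 1686 CPM (-2.54 ± 0.41, adjusted p = 0.0356).

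Also lower were IRF2BP2, a transcriptional corepressor (-1.67 ± 0.28, adjusted p = 0.0104), ABCA1, a cholesterol exporter (-1.92 ± 0.33, adjusted p = 0.0104), and ARRDC3, an arrestin-domain protein (-2.06 ± 0.39, adjusted p = 0.0356). TAOK1, a kinase upstream of stress-activated MAP kinases, was higher, at 81.4 ± 21.2 CPM against 12.4 ± 0.819 CPM (2.66 ± 0.52, adjusted p = 0.0356). In GRCh38 these genes lie on chromosome 13 from 99294530 to 99307405 (GPR183), 14 from 61695513 to 61748259 (HIF1A), 22 from 35380361 to 35394214 (HMOX1), 1 from 234604269 to 234609525 (IRF2BP2), 9 from 104781002 to 104928237 (ABCA1), 5 from 91368724 to 91383359 (ARRDC3) and 17 from 29390464 to 29551904 (TAOK1). In healthy donors GPR183 (149 and 171.9 CPM) and IRF2BP2 (230.5 and 319.3) lay within the FSGS range. So did HMOX1 (294.4 and 437.2) and ARRDC3 (170.2 and 171.9). TAOK1, at 34.39 and 97.53 CPM, was above both non-FSGS libraries. Healthy HIF1A (1346 and 1463 CPM) and ABCA1 (132.6 and 159.6) lay between FSGS and non-FSGS. The non-FSGS libraries thus lay apart from healthy donors as well, and which group departed was not tested in these cells. The HMOX1-led cluster described above held 65.9 ± 16.5% of the non-FSGS monocyte-like cells, against 36.4 ± 38.5% in primary and 3.88 ± 1.60% in secondary FSGS. Leaving out 1 library at a time gave 4 to 29 called genes, 29 of them without 1 of the 3 primary FSGS libraries, and without each of the 2 non-FSGS libraries in turn 2 and 5 of the 7 genes were still called. HMOX1 was at -1.24 and ARRDC3 at -1.41 without 1 of the 2 non-FSGS libraries.

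**Figure D3:**
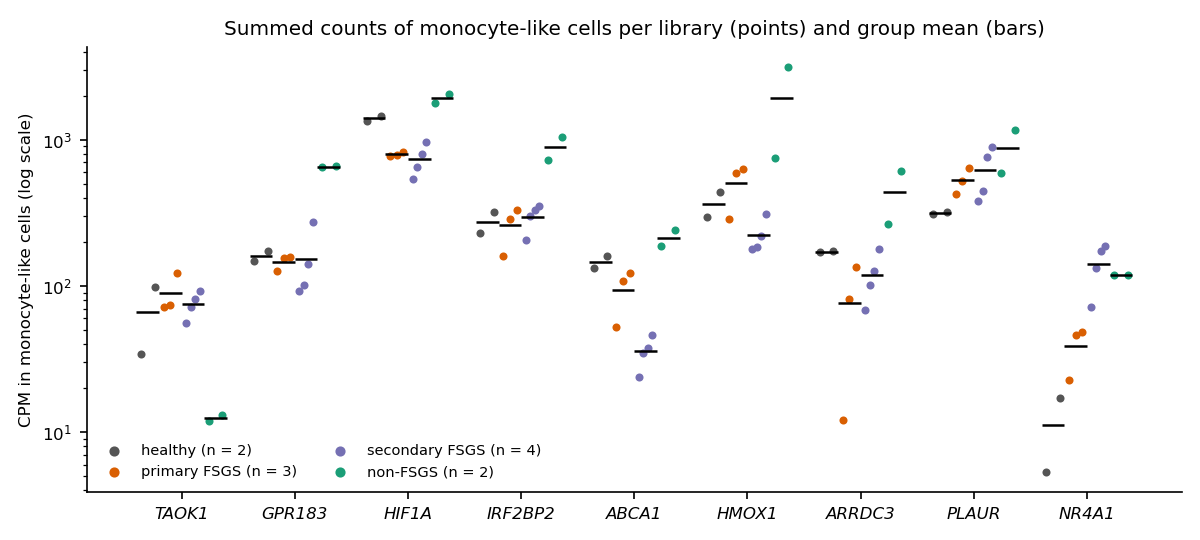
CPM in the summed counts of monocyte-like cells (log scale, vertical axis) for the 7 genes that differed between FSGS and non-FSGS and for PLAUR and NR4A1. Each point is a library and each bar a group mean; GPR183 averaged 654 CPM in non-FSGS and 150 CPM over the 7 FSGS libraries, and NR4A1 averaged 11.3 CPM in healthy donors and 102 CPM over the 9 patient libraries.

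As groups, mitochondrial transcripts and inflammatory genes fell in FSGS monocyte-like cells, and interferon response and nonclassical monocyte genes rose. All 13 mitochondrial transcripts were negative (median -0.54, adjusted p = 0.000687), with MT-ATP8 at -0.94 ± 0.30 and MT-CO3 at -0.59 ± 0.22, and none passed adjusted over the list alone. The inflammatory list had 9 of 10 negative (-1.003, 0.00466, 2 lower adjusted over the list alone), with OSM at -1.63 ± 0.53, VEGFA at -1.30 ± 0.44 and CXCL2 at -0.96 ± 0.37. The interferon list had 10 of 11 positive (0.64, 0.00466, 1 higher adjusted over the list alone), with the antiviral GTPase MX1 at 39.8 ± 23.9 CPM against 7.30 ± 1.94 CPM (2.22 ± 0.68) and ISG15 at 1.88 ± 0.66. The nonclassical list had 8 of 9 positive (1.22, 0.0108, 2 higher and 1 lower adjusted over the list alone), with SIGLEC10 at 1.55 ± 0.57, MS4A7 at 1.46 ± 0.54 and FCGR3A at 1.84 ± 0.72, while HES4 was at -2.11 ± 0.78. Adjusted p = 0.617 for the first 3 lists and 0.635 for the nonclassical list with an estimated correlation. With sums thinned to the smallest total the mitochondrial list alone passed, as the inflammatory and nonclassical lists had adjusted p = 0.147 and the interferon list too few genes to be tested. The interferon call ended without 1 of the 2 non-FSGS libraries (median log2 CPM difference 0.03) and the inflammatory call without the other (-0.957). The inflammatory call also ended without 1 secondary FSGS library (camera, adjusted p = 0.0609), and the nonclassical call without 1 primary FSGS library (adjusted p = 0.0612). PLAUR was at -0.64 ± 0.31 (adjusted p = 0.524).

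In all cells, stem and progenitor genes rose in FSGS relative to non-FSGS, with a median log2 fold change of 2.43, all 13 members positive and 6 higher adjusted over the list alone (camera, adjusted p = 4.86e-10; adjusted p = 0.707 with an estimated correlation). CRHBP measured 9.13 ± 5.60 CPM (n = 7) against 0.581 ± 0.382 CPM (n = 2) (4.10 ± 1.02), MEIS1, a homeobox factor of stem cells, was at 3.16 ± 0.82 and CD34 at 2.80 ± 0.81. CD34 was at 2.14 without 1 of the 2 non-FSGS libraries and CRHBP at 3.34 without the other. HSPC-like cells were 5.12 ± 2.43% of the FSGS cells and 0.681 ± 0.727% of the non-FSGS cells, at the smallest p that 36 splits can give (exact two-sided permutation test, p = 0.0278, adjusted p = 0.306). Monocyte-like cells were 22.1 ± 11.9% and 43.9 ± 30.6% (p = 0.111 in the same permutation test, adjusted p = 0.367), megakaryocyte-like cells 4.28 ± 1.86% and 1.13 ± 1.60%, and B progenitor-like cells 1.78 ± 2.64% and 0.0664 ± 0.0939%. The megakaryocyte-like class depends on the clustering. It held 283 cells at Leiden resolution 1 and 40 at resolution 2, where a cluster of 254 cells led by GATA2, SOX4 and ITGA2B was unnamed.

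Beside these shares, 8 further lists passed in all cells. Platelet genes rose (median 2.33, 9 of 11 positive, adjusted p = 0.00228, 1 higher adjusted over the list alone; CLU 2.44 ± 0.52, ITGA2B 2.33 ± 0.86, SPARC 1.56 ± 0.54), as did B progenitor genes (1.53, 8 of 9 positive, 0.00228, 1 higher adjusted over the list alone; IGLL1 1.76 ± 0.87, PAX5 1.53 ± 0.77) and ribosomal protein genes (0.22, 20 of 23 positive, 0.0318; RPL3 0.50 ± 0.19, RPS18 0.42 ± 0.18). Inflammatory genes fell (-1.71, 12 of 13 negative, 0.000680, 7 lower adjusted over the list alone), with CXCL8 at -2.88 ± 0.74, CXCL2 at -2.41 ± 0.53 and VEGFA at -1.98 ± 0.49. The uPAR list fell (-1.11, 9 of 10 negative, 0.00322), with PLAUR at 85.6 ± 29.4 CPM against 251 ± 146 CPM (-1.59 ± 0.37, lower in 7 of 7, the 1 member passing adjusted over the list alone), the plasminogen activator inhibitor SERPINB2 at -2.27 ± 0.79 and FPR1 at -1.54 ± 0.62. Calprotectin and alarmin genes fell (-0.65, 9 of 9 negative, 0.00548; S100A10 -1.43 ± 0.52, S100A4 -0.76 ± 0.36), as did NF-kB targets (-0.59, 10 of 15 negative, 0.0156, 2 lower adjusted over the list alone; ICAM1 -2.54 ± 0.57, IER3 -2.32 ± 0.53) and erythroid genes (-0.91, 15 of 17 negative, 0.0205; SLC4A1 -2.11 ± 0.95). With an estimated correlation, adjusted p = 0.849 for the inflammatory, platelet, B progenitor, uPAR and calprotectin lists and 0.876 for the NF-kB, erythroid and ribosomal lists. With the preset correlation, other splits of the 7 FSGS libraries called up to 20 lists in all cells. Platelet and B progenitor genes passed without each library in turn. Without 1 of the 2 non-FSGS libraries the uPAR, calprotectin, inflammatory, NF-kB and ribosomal calls ended. Their median log2 CPM differences were then -0.205, -0.487, -0.141, 0.078 and 0.1. Without the other the erythroid and ribosomal calls ended, with 0.155 and 0.311. NF-kB and erythroid genes thus no longer fell in these fits. The NF-kB call also ended without 1 primary FSGS library (camera, adjusted p = 0.0904). The erythroid call ended without 1 primary (adjusted p = 0.167) or 1 secondary FSGS library (adjusted p = 0.0856). The ribosomal call ended without 1 primary (adjusted p = 0.302) or 1 secondary FSGS library (adjusted p = 0.0825), and without 1 healthy library (median log2 CPM difference 0.192). Over all 11983 genes edgeR called 0, with 1073 at an unadjusted p under 0.05, whereas DESeq2 called 68, and 126 genes were called by edgeR without 1 of the 2 non-FSGS libraries. Much of the fall rests on 1 of the 2 non-FSGS libraries, without which log2 fold changes were -1.21 for CXCL8, -0.77 for CXCL2, -0.85 for VEGFA, -0.72 for ICAM1, -1.24 for IER3, -0.86 for PLAUR, -0.62 for FPR1 and 0.09 for S100A10, and the rise of ITGA2B and IGLL1 was 1.57 and 1.11. IGLL1 also fell to 1.13 without 1 of the 4 secondary FSGS libraries, and SLC4A1 turned to 0.81 without the other non-FSGS library.

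The third comparison asked whether primary and secondary FSGS differ. In all cells, naive T cell genes rose in primary FSGS, with a median log2 fold change of 0.77 and 10 of 12 positive (camera, adjusted p = 0.00506). CCR7, a homing receptor of naive T cells, measured 121 ± 111 CPM in primary (n = 3) and 15.4 ± 12.6 CPM in secondary FSGS (n = 4) (3.02 ± 0.94), PIK3IP1 was at 1.88 ± 0.60, the interleukin 7 receptor IL7R at 1.93 ± 0.80 and the costimulatory receptor CD28 at 1.86 ± 0.81. These 4 were at 2.14, 0.92, 1.30 and 1.21 without 1 of the 3 primary FSGS libraries. T-like cells were 23.1 ± 14.9% of the primary and 8.30 ± 5.97% of the secondary FSGS cells (exact two-sided permutation test, p = 0.171, adjusted p = 0.943). Ribosomal protein genes rose (0.20, 23 of 23 positive, 0.0182; RPS14 0.28 ± 0.17, RPL10 0.27 ± 0.17) and heat shock genes fell (-0.42, 12 of 13 negative, 0.0182; HSPA1A -1.24 ± 0.52, DNAJA1 -0.50 ± 0.28). No member of these 3 lists passed over all genes or adjusted over the list alone, and adjusted p = 0.976 for each list with an estimated correlation. All 3 calls ended without 1 of the 3 primary FSGS libraries (0.0699 for naive T and heat shock, 0.898 for ribosomal genes). The heat shock call also ended without another primary (0.107) or 1 secondary FSGS library (0.133) and with thinned sums (0.0552), and the ribosomal call without that secondary FSGS library (0.081). Each of the 35 ways to divide the 7 FSGS libraries into 3 and 4 called at least 3 lists, so that the number of lists does not set the labelled groups apart. PLAUR was at -0.36 ± 0.39. Among 11983 genes edgeR called 0, with 473 at an unadjusted p under 0.05, and DESeq2 called 1.

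In monocyte-like cells, classical monocyte genes (median -0.41, 9 of 11 negative) and glucocorticoid response genes (-0.98, 11 of 11 negative) fell in primary relative to secondary FSGS (camera, adjusted p = 0.0463 for both, and 0.955 for both with an estimated correlation). CLEC4E, a receptor for damaged cells and mycobacteria, was at 49.4 ± 48.7 CPM in primary (n = 3) and 166 ± 61.3 CPM in secondary FSGS (n = 4) (-1.38 ± 0.49) and FCN1 at -0.49 ± 0.27. Of the glucocorticoid response genes, TXNIP was at -1.14 ± 0.58, KLF9 at -1.34 ± 0.83 and the clock gene PER1 at -1.16 ± 0.85, and no member of either list passed adjusted over the list alone. Both calls ended without 1 of the 2 healthy libraries (0.0527), without 1 primary FSGS library (0.297 for classical monocyte, 0.162 for glucocorticoid response genes), and without each of 3 of the 4 secondary FSGS libraries, not the same 3 for both lists (0.0584, 0.0711 and 0.077, and 0.0711, 0.209 and 0.099), the latter also without another primary FSGS library (0.336). Of the 35 ways to divide the 7 FSGS libraries into 3 and 4, 20 called at least 2 lists. The S100A9-led cluster held 29.1 ± 50.4% of the primary and 63.7 ± 35.8% of the secondary FSGS monocyte-like cells. PLAUR was at -0.24 ± 0.31 (adjusted p = 0.913). Of 6230 genes, 1 was called by edgeR, lower in primary FSGS, and it is not named because its level is known to follow a common inherited variant, and no test here separates persons from disease for it. DESeq2 called 16, and 212 genes were called by edgeR without 1 of the 3 primary FSGS libraries.

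**Figure D4:**
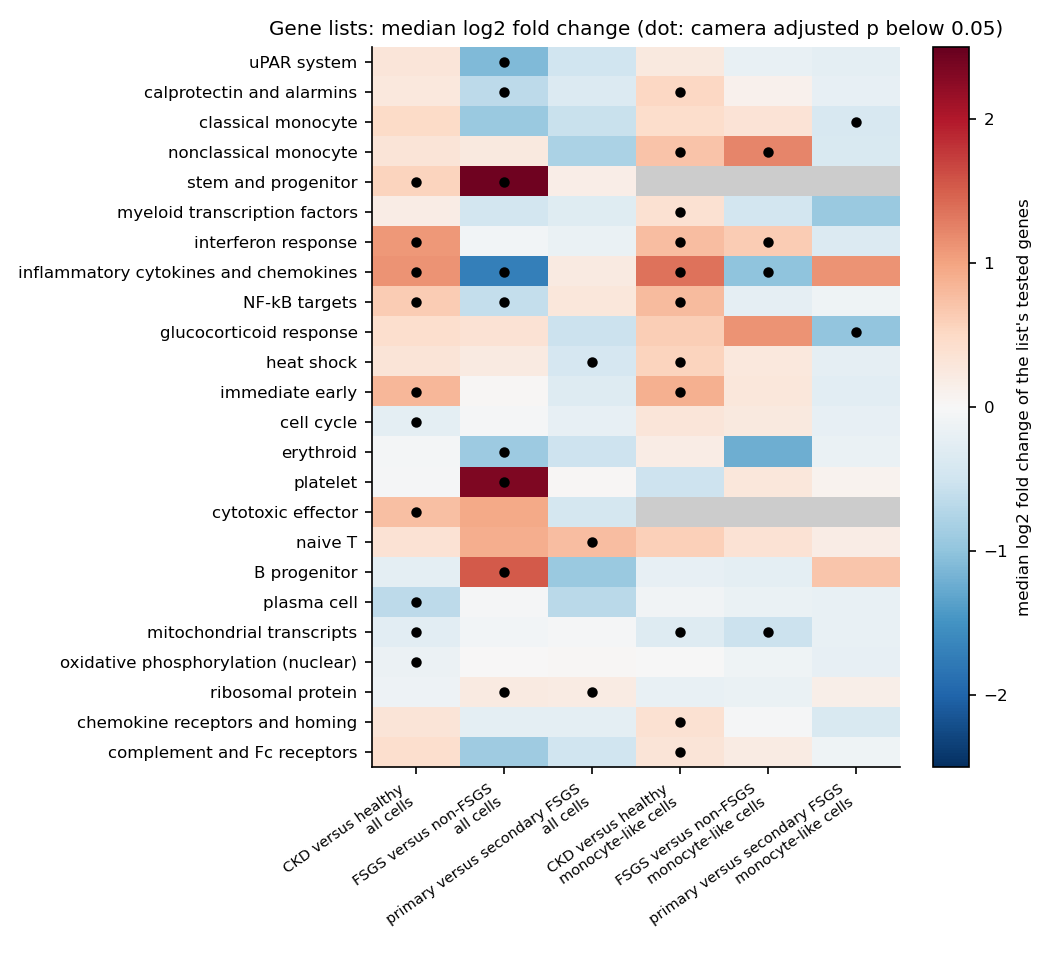
Median log2 fold change (colour) of the tested members of each fixed gene list (rows) in the 3 comparisons, in all cells and in monocyte-like cells (columns). Lists with a call in at least 1 column are drawn, black dots mark camera adjusted p under 0.05 with the preset correlation, and grey marks a list with too few tested genes; the median was 2.43 for stem and progenitor genes in FSGS versus non-FSGS and 1.37 for inflammatory genes in monocyte-like cells of CKD patients.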

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

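No test in this part was chosen after its result was seen. Among the 4 secondary FSGS libraries, the 1 group tested, as groups under 4 libraries were left out, 8 of 106 values (shares of the classes and CPM of the named genes) had 1 library far from the other 3, by Dixon's ratio of the gap to the whole range. Chance gives about 1 in 20 such values. In all cells the gap was 0.855 of the range for CCL2, 0.845 for CXCL2, 0.906 for GZMA, 0.977 for IGLL1 and 0.914 for MT-CYB. In monocyte-like cells it was 0.834 for CD83, 0.846 for IL1B and 0.905 for S100A10.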

How the results depend on the processing

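Chosen only after the data had been seen were the removal of barcodes 1 mismatch from a larger barcode of the same library, the omission of the 3 libraries under 650 kept cells, and the relaxed rule for myeloid progenitor-like cells (1 non-FSGS library) and erythroid-like cells (a minimum of 10 cells), where the planned rule of 20 cells in 2 libraries per group could not be run. The fit of the compared groups only is the same fit for CKD versus healthy. No class share passed under any alternative, but no single class could have, so stability stays open. PLAUR in monocyte-like cells of CKD patients stayed positive and unpassed over all genes under all alternatives, from 0.96 to 1.15, and from 0.81 to 1.19 leaving out 1 library. Of 2226 alternative values of the named genes, 2123 kept direction and threshold side, but most had no call to lose. Another 34 lost a call, 60 gained one and 9 changed sign. Of 114 named gene changes, 31 came nearer to 0 by over 1.5-fold without 1 library, 20 of them without 1 of the 2 non-FSGS libraries. In simulated data 2-fold changes were mostly missed.

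Without the filter on low counts edgeR called 38 genes for CKD versus healthy, 380 for FSGS versus non-FSGS, 128 for primary versus secondary FSGS, and 62, 81 and 89 for primary FSGS, secondary FSGS and non-FSGS versus healthy in all cells. In monocyte-like cells it called 20, 85 and 43 in the first 3 comparisons, and 1 in B-like, 4 in myeloid progenitor-like and 3 in erythroid-like cells. DESeq2 called 68, 1, 2 and 1 genes in all cells for FSGS versus non-FSGS, primary versus secondary FSGS, secondary FSGS versus healthy and non-FSGS versus healthy. In monocyte-like cells it called 11, 19 and 16, and it called 0 in myeloid progenitor-like and 0 in erythroid-like cells (120 and 62 at its unadjusted p under 0.05), where edgeR called 1 each and, with RLE scaling, 3 in the latter. With at least 500 genes per cell 1 gene was called for CKD versus healthy in monocyte-like cells. Without the libraries under 650 kept cells 1 gene was called there, 0 for primary versus secondary FSGS, and 1 list for the latter. Lists called with all libraries lost their call there in all cells for CKD versus healthy (inflammatory 0.0927, NF-kB 0.997, cell cycle 0.465, cytotoxic 0.257, oxidative phosphorylation 0.201), FSGS versus non-FSGS (uPAR 0.44, calprotectin 0.484, inflammatory 0.316, NF-kB 0.389, ribosomal 0.998) and primary versus secondary FSGS (heat shock 0.0629, ribosomal 0.308). In monocyte-like cells they were, in the same order of comparisons, nonclassical 0.0733, transcription factors 0.0623 and heat shock 0.0549, nonclassical 0.182, and classical monocyte 0.601 (all adjusted p). With thinned sums 0 genes were called for primary versus secondary FSGS in monocyte-like cells, and lists fell to 6 for CKD versus healthy and 1 for FSGS versus non-FSGS. All 6 counts of called lists went to 0 with an estimated correlation and to 0 with fry. The causes were not tested.

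With the label number as a block, 365 genes were called between primary FSGS and healthy donors over the 2 shared numbers, against 0 without it. The deviations of same-numbered libraries correlated at 0.439 for number 1 and -0.082 for number 2, and the numbers name different persons, so that they do not pair the libraries.

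Leaving out 1 library at a time gave 0 to 1 genes in all cells for CKD, primary FSGS and secondary FSGS versus healthy (1 without the same 1 of the 4 secondary FSGS libraries). It gave 0 to 126 for FSGS versus non-FSGS (126 without 1 of the 2 non-FSGS libraries, 1 without 1 secondary FSGS library), 0 to 3 for non-FSGS versus healthy (3 without the same non-FSGS library) and 0 in every fit for primary versus secondary FSGS. In monocyte-like cells, CKD versus healthy ranged from 0 to 8 (8 without 1 of the 3 primary FSGS libraries, 2 and 4 without each non-FSGS library) and FSGS versus non-FSGS from 4 to 29 (29 and 11 without 1 primary FSGS library each, 26 without 1 secondary FSGS library, 4 without each of the other 3, and 11 without 1 of the 2 healthy libraries). Primary versus secondary FSGS ranged there from 0 to 212 (212 without 1 primary FSGS library, 0 without another or without any of 3 secondary ones).

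In the other classes, leaving out a library gave 0 in every fit in T-like cells and 0 to 1 genes in cytotoxic lymphocyte-like cells (1 without 1 primary FSGS library). B-like cells gave 0 to 2 (2 without 1 primary FSGS or 1 non-FSGS library, 1 without 1 healthy, 2 secondary FSGS or the other non-FSGS library), and myeloid progenitor-like cells 0 to 3 (0 without 1 healthy, 2 without 1 primary FSGS and 3 without 1 secondary FSGS library). Erythroid-like cells gave 0 to 39 (0 without either healthy library, 39 and 15 without each non-FSGS library, 5 and 2 without 1 primary FSGS library each, 5 and 2 without 1 secondary FSGS library each). Called lists ranged in all cells from 8 to 15 for CKD versus healthy, 7 to 12 for FSGS versus non-FSGS and 2 to 10 for primary versus secondary FSGS (10 and 5 without 1 primary FSGS library each, 9, 8 and 6 without 1 secondary FSGS library each). In monocyte-like cells they ranged from 7 to 13 for CKD versus healthy (7 without 1 healthy library), 3 to 6 for FSGS versus non-FSGS and 0 to 3 for primary versus secondary FSGS (0 without 1 healthy, 1 primary FSGS or 2 secondary FSGS libraries, 1 without another primary or another secondary FSGS library). A fit with 1 library in a group assumes that it varies like the other groups.

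Of the 7 genes called between FSGS and non-FSGS monocyte-like cells, GPR183 was called under all alternatives and without each library in turn, and each of the other 6 was lost under 1 or more, most often TAOK1. The log2 fold change of TAOK1 stayed at 2.47 to 2.74 leaving out 1 library, while that of HMOX1 ranged from -3.29 to -1.24. S100A10 in FSGS versus non-FSGS, all cells, turned to 0.12 without the libraries under 650 kept cells and ranged from -2.14 to 0.0858 leaving out 1 library (the latter without 1 non-FSGS library), and SLC4A1 from -3.01 to 0.81 (without 1 non-FSGS library). PLAUR in primary FSGS versus healthy, 0.06 in the report, was -0.0026 without the low-count filter, -0.0651 with at least 500 genes per cell, -0.0135 without 1-mismatch barcodes, -0.0335 without the libraries under 650 kept cells, and from -0.24 (without 1 healthy library) to 0.42 leaving out 1 library, with -0.0345 without 1 primary FSGS library.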

Other observations

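In this part the list tests in classes other than monocyte-like cells, the tests of depth, the tests of a single library for the immediate early and mitochondrial lists, and the splits by count of genes were chosen only after the results they bear on were seen. Beyond monocyte-like cells, immediate early genes were higher in patients than in healthy donors in several lineages. The list rose in cytotoxic lymphocyte-like cells (median log2 fold change 0.87, 13 of 13 positive, camera adjusted p = 7.63e-06), in B-like cells (0.62, 12 of 13, 0.00133), in myeloid progenitor-like cells (0.64, 14 of 16, 0.000157) and in erythroid-like cells (0.77, 10 of 11, 0.0478), while T-like cells gave 0.56 (12 of 13, 0.0657). With an estimated correlation, adjusted p = 0.201, 0.541, 0.990 and 0.769 for the 4 calls.

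In T-like cells ribosomal protein genes fell (median -0.29, 23 of 23 negative, adjusted p = 0.000907, and 0.654 with an estimated correlation), as did nuclear genes of oxidative phosphorylation (-0.28, 13 of 16 negative, 0.0117, and 0.536). In B-like cells NF-kB targets rose (0.74, 7 of 9 positive, 0.00133, and 0.0903 with an estimated correlation), as did the genes of MHC class II expression (0.61, 3 of 3 positive, 0.0438, and 0.541). Mitochondrial transcripts fell in erythroid-like cells (-0.68, 13 of 13 negative, 4.61e-06, and 0.769) and in cytotoxic lymphocyte-like cells (-0.33, 11 of 13 negative, 0.0470, and 0.676). Differences between lineages were not tested.

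The higher immediate early genes in monocyte-like cells of patients may reflect the handling of the cells before sequencing, since such genes respond to warming, dissociation and thawing. Handling would act on other cell types too, and the mean of the list's medians over T-like, cytotoxic lymphocyte-like and B-like cells was 0.68 (SD 0.16), above 0.5 of the monocyte-like median (0.44). The list still passed with thinned sums (camera, adjusted p = 0.000293) and without each library in turn (3.04e-10 to 0.000492). The call thus needed neither the full depth of the sums nor any 1 library. Both checks used the preset correlation, and with an estimated correlation the list had adjusted p = 0.169. With the preset correlation, other splits of the 7 FSGS libraries called up to 7 lists in monocyte-like cells. Deviating libraries are therefore not excluded as a cause. Handling, the source of the healthy marrow, the patients' kidney transplant and the disease itself stay open, because all healthy libraries share a source and all patients had a transplant.

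The 7 genes that differed between FSGS and non-FSGS monocyte-like cells rest on 2 non-FSGS libraries. If 1 of those were the cause, most genes would lose their change without it, and 6 of 7 kept at least 0.5 of their log2 fold change in the worse of the 2 fits, with 2 genes still called there and 5 in the other. The genes had been chosen for passing with both libraries, which favours genes on which these 2 agree. The test therefore excludes neither a single library nor a difference between the persons. RNA of red cells in these sums, measured as HBB, was at 250 ± 175 CPM in FSGS and 697 ± 871 CPM in non-FSGS (-1.43 ± 1.11), a difference too uncertain to decide anything, and HBB does not measure heme, which induces HMOX1. The disease label stays among the open explanations.

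The lower mitochondrial transcripts of patients could come from handling as well. Over the 3 lymphocyte classes the mean of the list's medians was -0.12 (SD 0.18), against -0.16 for 0.5 of the monocyte-like median, so that handling and disease cannot be told apart for this list. A single library is not shown to be the cause in all cells. Without 1 of the 2 healthy libraries the adjusted p rose to 0.204 (7.37e-05 to 0.204 leaving out each in turn), but the median log2 CPM difference was -0.23 (quartiles -0.35 and -0.14), as with all libraries (-0.23, quartiles -0.45 and -0.19), and the median nearest 0 in any fit was -0.17 (quartiles -0.40 and -0.10).

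Between primary and secondary FSGS in all cells the real split called 0 genes (88 at most in another), so that all 35 splits of the 7 FSGS libraries into 3 and 4 reach that count by construction, and it says nothing about chance. For the other 3 counts chance could not be excluded. All 35 splits gave at least the 3 lists of the real split in all cells (20 at most in another). In monocyte-like cells 4 splits gave as many genes as the 1 of the real split (106 at most in another) and 20 gave as many lists as the 2 of the real split (7 at most in another). Splits that call many more genes than the real one point to a structure of the samples, which may be no more than 1 deviating library, as 212 genes were called in monocyte-like cells without 1 primary FSGS library. Its source was not tested.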
